A study of Homo sapiens with 15 samples.

How the data were processed

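Poly(A)-selected RNA from THP-1 cells, a human monocytic leukemia line, was sequenced after the cells had been turned into immature dendritic cells. Per the labels' protocols, the cells grew for 5 days with interleukin-4 and GM-CSF at 1500 U/mL each. They were then exposed for 24 h in medium with 5% delipidated serum. There were 5 groups of 3 samples each, 15 libraries in all, grouped by the treatment given in the labels: vehicle control (0.1% DMSO), PFOA, PFOS, dexamethasone (DEX) and GW7647. The share of DMSO in the treated groups is not given in the sources used here, so a difference in vehicle cannot be separated from any difference between a treated group and control. The labels number the replicates but do not say that they came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical. The series' design text speaks of 2 independent sequencing experiments, and only the libraries described here were analysed.

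The authors deposited 1 table of normalized reads for 62649 genes. Its values are a signal that is never negative: reads per gene divided by 1 size factor per library, as the deposited values themselves show. Each column is made of whole multiples of its smallest step, and dividing by that step gave whole reads for 100% of values in each library, at a tolerance of 0.001 read. The submitters' processing notes name cutadapt 1.16, HISAT2 2.2.1, SAMtools 1.9, HTSeq 0.11.2, limma 3.50.3, edgeR 3.36.0 and the genome build GRCh38.p13, with no role for each. The tool that gave the size factors, and whether the counting used strand, are not given in the sources used here. The deposited factors equal median-of-ratios factors computed from the recovered reads, with a spread of 0.000882%. Because that scaling takes the typical gene as unchanged, a change shared by most genes would not show.

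Recovered reads per library ran from 36.5 to 43.3 M, and size factors from 0.909 to 1.13. Reads without molecular identifiers are not independent molecules, so intervals from counts cover counting error only. Gene symbols were matched for 42300 of the 62649 gene identifiers. Coordinates and gene types come from GENCODE release 29 on GRCh38, which holds 58225 genes. No value column was left without a sample (0 columns).

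Differences between groups were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1). Genes with a value of at least 1 in at least 3 of the 15 samples were kept, which left 29545. Of the others, 22410 had no read in any library. A single fit of all 15 samples shared 1 estimate of the spread per gene (limma's trend method), and p-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. The comparisons were each of the 4 treatments against control, PFOS against PFOA, each of PFOA and PFOS against GW7647 and against DEX, and an F test for any difference among the 5 groups. No design or test had to be changed once the unit of the values was known. These choices, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

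The rule names, per comparison, up to 12 genes of largest increase and 12 of largest decrease that passed the threshold, have a symbol, had groups that did not overlap, and reached at least the median level in their higher group. Where no gene passed, it names the 5 of lowest p. It adds a fixed set of PPAR, glucocorticoid, sterol, dendritic cell and receptor genes in every comparison, and up to 4 members of lowest p for each list described. A member named in the text because it went against the rest of its list was chosen after its value was seen.

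Of 33 fixed gene lists, the 31 with at least 4 tested members were tested with camera from limma, at a preset correlation between genes of 0.01 and adjusted over the lists of each comparison. The lists of epithelial markers (2 members tested) and erythroid markers (0 tested) were left out. The other lists cover metabolism (PPAR targets and fatty acid oxidation, cholesterol biosynthesis and uptake, fatty acid synthesis and desaturation, LXR targets, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrial genome transcripts), hormone and stress responses (glucocorticoid receptor targets, metallothioneins, NRF2 targets, aryl hydrocarbon receptor targets, unfolded protein and integrated stress response, p53 targets, cell cycle, lysosome) and immunity (MHC class I, MHC class II, dendritic cell maturation, IL-4 response and immature dendritic cell genes, inflammatory cytokines and NF-kB targets, type I interferon response, tolerogenic genes, phagocytic receptors, toll-like receptors, complement). A further group holds markers of monocytes, macrophages, dendritic cells, osteoclasts, lymphocytes and fibroblasts. Each list was also tested with a correlation estimated from its own genes, and with fry. Similarity of responses was given as the correlation and covariance of fold changes across genes. Beside them stand values from 100 simulations of unchanged groups sharing the 3 control libraries, in which genes varied independently of each other.

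The replicate numbers in the labels might pair samples, so the correlation of same-numbered samples' deviations from their group means was computed over 12143 genes. By a limit of 0.1 for every pair, the numbers paired the samples in PFOS against control (correlations 0.219 to 0.382), GW7647 against control (0.258 to 0.475) and PFOS against PFOA (0.230 to 0.381), and in no other comparison. No 2 libraries of a group were alike to within sampling noise: the chi-square per degree of freedom of their reads ran from 3.68 to 16.3.

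The alternatives fixed in advance were pseudocounts of 0.25 and 4, no filter or a filter at 5, median-of-ratios scaling, quantile normalization, the replicate number as a block, fits of the compared groups alone, robust variance estimates, array weights, each replicate left out in turn, a threshold of 0.01, and edgeR 4.0.16 (quasi-likelihood test, 18670 genes) and DESeq2 1.42.0 on the recovered reads. Scaling by TMM, limma's voom, the share of mitochondrial reads as a covariate and a fit without the DEX samples were chosen after seeing the data. The limma step was tested on simulated reads, with 50 changed genes at each of 4 fold changes, for PFOA against control and for PFOS against control. The changed genes were drawn only from genes above a set mean level, so the shares recovered do not hold for lower genes. In the first it recovered 46% of genes changed 1.25-fold, 80% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, and called 8 of 29345 unchanged genes. In the second these were 46%, 74%, 82% and 100%, with 2 of 29345 unchanged genes called. In a simulation of 30 lists for each of the same comparisons, 1 of them changed, the changed list was called and 0 unchanged lists were, with either correlation. Simulated genes varied independently, so this could not test lists whose genes move together, such as the interferon list (estimated correlation 0.549). Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.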

Results

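Expression was measured by poly(A) RNA sequencing in 15 libraries of THP-1-derived immature dendritic cells, 3 libraries in each of 5 groups. The groups were a vehicle control (0.1% DMSO), 10 µg/mL PFOA (perfluorooctanoic acid, 24.4 µM), 10 µg/mL PFOS (perfluorooctanesulfonic acid, 20 µM), 150 µg/mL DEX (dexamethasone, a synthetic glucocorticoid) and 1 µM GW7647 (an agonist of the nuclear receptor PPARα). Libraries held 36.5 to 43.3 M reads, with 26579 to 28871 genes detected. Mitochondrial transcripts took 2.21% to 2.32% of reads in control, 2.28% to 2.49% with PFOA and 2.2% to 2.42% with PFOS. That share varied more in DEX (2.01% to 2.98%) and in GW7647 (1.83% to 2.67%). The 50 most abundant genes held 13.6% to 15% of reads. Below, levels are normalized reads as mean ± SD of 3 libraries, log2 changes are given ± standard error or with a 95% interval in square brackets, adjusted p-values of single genes are from limma, and those of lists are from camera.

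PFOA raised 3 genes of fatty acid use and storage in these cells. PDK4, a kinase that holds back glucose oxidation, rose most, followed by the lipid droplet protein PLIN2 and the mitochondrial fatty acid importer CPT1A. Genes of type I interferon response leaned lower as a list, and the co-stimulatory and antigen-presenting genes examined showed no detectable change. The comparison asks how the carboxylate PFAS acts on immature dendritic cells. Of 29545 genes tested, 3 rose and 0 fell in limma, with 1163 at an unadjusted p under 0.05 where 1477 were expected by chance. That shortfall does not show that no other gene changed. With edgeR the counts were also 3 and 0, with DESeq2 7 and 7. Quantile normalization gave 3 higher and 1 lower, adding MX1. The replicate block, also fixed in advance, gave 6 higher and 2 lower, adding SIGLEC1, IFI44L, CD300A, FABP4 and MCEMP1.

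PDK4 (ENSG00000004799, GRCh38 chromosome 7, 95583499 to 95596491) rose 3.92-fold, from 116 ± 10.7 to 457 ± 47.0 normalized reads (log2 change 1.97 ± 0.09, adjusted p = 8.2e-13). PLIN2 (ENSG00000147872, chromosome 9, 19108375 to 19149290) rose 2.05-fold, from 9796 ± 525 to 20063 ± 1182 (1.03 ± 0.07, adjusted p = 5.1e-10). CPT1A (ENSG00000110090, chromosome 11, 68754620 to 68844410) rose 1.26-fold, from 4267 ± 91.6 to 5369 ± 138 (0.33 ± 0.05, adjusted p = 0.0037). The CPT1A call was lost without control replicate 2 (adjusted p = 0.0641) and when PFOA and control were fitted alone (adjusted p = 0.313). All 3 are annotated on the minus strand. Other PPAR targets did not pass in limma's main fit. FABP4 averaged 153 ± 45.8 against 84.0 ± 9.99 reads (adjusted p = 0.31). It passed with the replicate block (0.0216), without PFOA replicate 3 (0.0018) and with the mitochondrial share as a covariate (0.022). DESeq2 called the PPAR list members ACADVL, HADHB and ACAA2, and ACADVL also passed with that covariate. ANGPTL4 averaged 28.5 ± 1.94 against 16.7 ± 2.86 (adjusted p = 0.74). Log2 changes were 0.17 for CD36, 0.34 for PPARG and 0.00 for PPARA, none past the threshold. The dendritic cell genes CD86 (-0.04), CD83 (0.10), HLA-DRA (0.06), CD209 (-0.02) and CD1A (0.01) did not pass either, nor did the glucocorticoid target FKBP5 (0.00) or the oxidative stress gene HMOX1 (0.01).

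Among gene lists, PPAR targets lay higher and interferon genes lower with PFOA than in control, and these are the 2 list calls that held with an estimated correlation. The interferon list also lay below control in every library of DEX (medians -0.38 to -0.15) and GW7647 (-0.14 to -0.12). High control libraries therefore cannot be told apart from an effect of PFOA on it. The PPAR list had 3 of 24 tested members higher over all genes and 15 when adjusted over the list alone. Its median log2 change was 0.17, with 21 members positive (adjusted p = 3.8e-33, and 0.000894 with an estimated correlation). In the interferon list, 0 of 23 members fell over all genes by limma, but 22 fell when adjusted over the list alone. All 23 had negative changes, with a median of -0.24 (adjusted p = 1.2e-43, and 0.0237 with an estimated correlation). Its members MX1 (-0.33), IFI44L (-0.42), RSAD2 (-0.41) and IFI44 (-0.29) had adjusted p between 0.16 and 0.31 in limma. DESeq2 called all 4 (adjusted p = 0.0020, 0.019, 0.019 and 0.048). MX1 also passed with quantile normalization (0.0432), robust variance estimates (0.0458), array weights (0.0444) and the mitochondrial share as a covariate (0.0314). IFI44L passed with that covariate (0.0430) and with the replicate block (0.0250). Cholesterol genes leaned up by a median of 0.10 (adjusted p = 1.5e-08, but adjusted p = 0.269 with an estimated correlation), as did fatty acid synthesis genes, by 0.04 (adjusted p = 0.00154, but adjusted p = 0.287 with an estimated correlation). Mitochondrial transcripts (0.10), monocyte markers (-0.06) and osteoclast markers (0.20) also passed only at the preset correlation (adjusted p = 0.0082, 0.0152 and 0.0311, against adjusted p = 0.915, 0.269 and 0.212 with an estimated correlation). Leaving out PFOA replicate 2 ended these last calls (adjusted p = 0.0743, 0.170 and 0.207). Control replicate 3 ended the monocyte (0.156) and osteoclast (0.0529) calls when left out, and control replicate 1 the osteoclast call (0.0929). The other 24 lists had adjusted p from 0.0708 to 0.939.

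**Figure D1:**
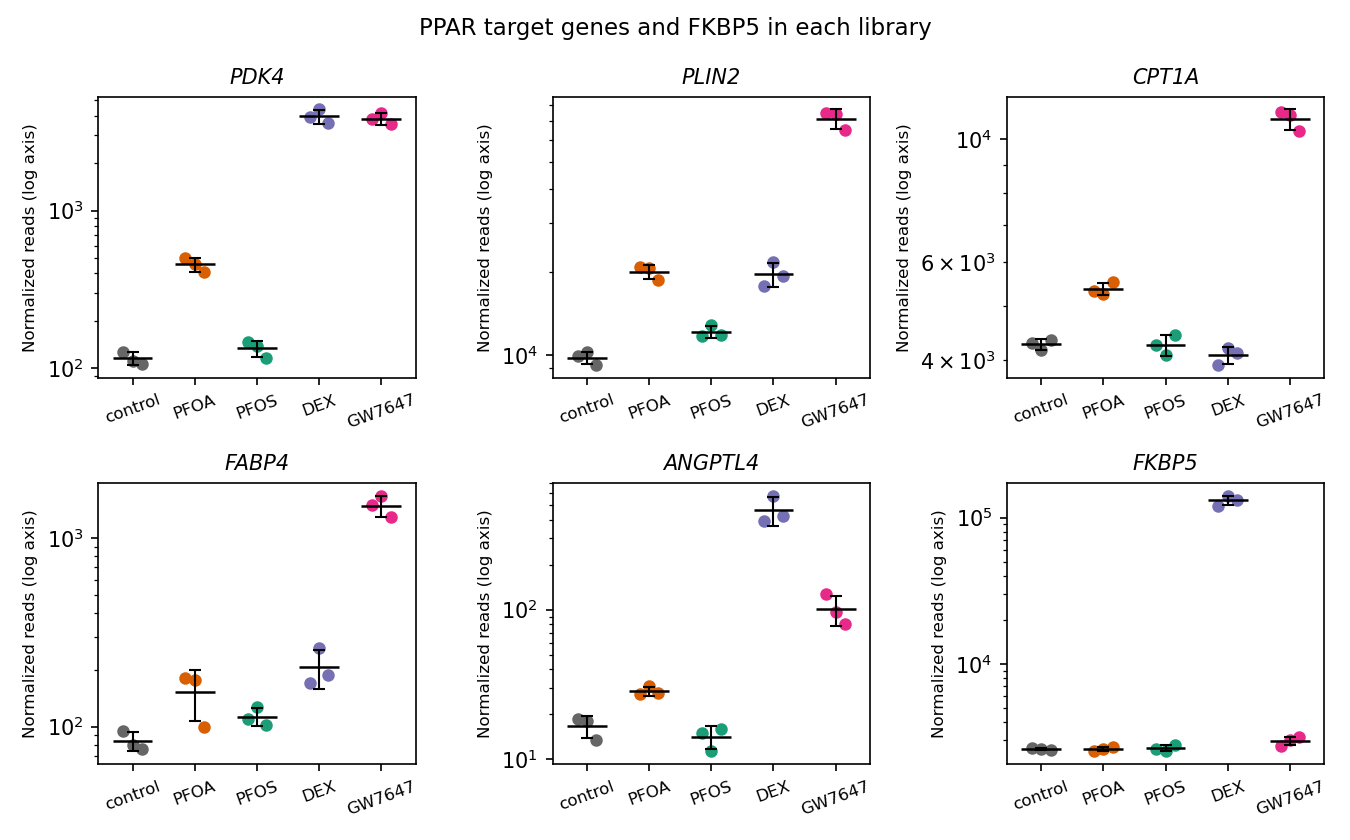
Normalized reads on a log axis of PDK4, PLIN2, CPT1A, FABP4, ANGPTL4 and FKBP5 in the 5 groups; points are libraries, lines are means and bars are SD of 3 libraries. PDK4 averaged 116 in control, 457 with PFOA, 134 with PFOS, 3960 with DEX and 3818 with GW7647.

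With PFOS, no single gene passed the threshold in limma's main fit. The genes nearest to it included the leukotriene pathway gene ALOX5AP and the phagocytic receptor MERTK on the higher side, and the interferon-related MX1, TRIM22 and STAT2 on the lower side. As a list, interferon genes lay below control about as far as with PFOA. Since the list also lay lower with DEX and GW7647, high control libraries cannot be told apart from an effect of PFOS. This comparison asks the same question for the sulfonate PFAS. By limma's main fit 0 genes passed, with 1191 at an unadjusted p under 0.05 where 1477 were expected by chance. That fit leaves out the pairing of these samples by replicate number, so neither count shows that no gene changed. With the replicate block 4 genes passed. By edgeR 0 passed, and by DESeq2 3 were higher and 10 lower.

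The 5 genes of lowest p, none past the threshold in limma, were ALOX5AP (7917 ± 621 against 6398 ± 357 reads, log2 change 0.31), MX1 (8442 ± 796 against 10531 ± 440, -0.32), MERTK (799.6 ± 24.7 against 617 ± 53.7, 0.38), TRIM22 (2222 ± 211 against 2779 ± 147, -0.33) and STAT2 (3061 ± 232 against 3671 ± 205, -0.26). Their adjusted p ran from 0.28 to 0.29. DESeq2 called all 5 (adjusted p = 0.0087, 0.0089, 0.0147, 0.0147 and 0.0163), and ALOX5AP (0.0410) and MX1 (0.0276) also passed with the mitochondrial share as a covariate. With the replicate number as a block, which pairs these samples, 4 genes passed: ALOX5AP, PLIN2 and TGM2 higher and IFI44L lower (each with adjusted p = 0.046). IFI44L also passed with DESeq2 (adjusted p = 0.0416) and without PFOS replicate 1 (0.0453), and PLIN2 with DESeq2 (0.0177) and with the mitochondrial covariate (0.0195). PLIN2 averaged 12151 ± 602 reads (log2 change 0.31 [0.17, 0.45], adjusted p = 0.35 without the block). For PDK4 the change was 0.20 [0.01, 0.40] and for CPT1A -0.01 [-0.11, 0.09], neither past the threshold. FKBP5 (0.02), CD209 (-0.01), CD86 (-0.06), CD83 (-0.02), HLA-DRA (0.05) and HMOX1 (0.10) did not pass.

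The interferon list had 0 of 23 members past the threshold over all genes by limma, 21 lower when adjusted over the list alone, and all 23 negative. DESeq2 called 5 members: MX1, STAT2, IRF7 (adjusted p = 0.0163), IFI44L and XAF1. The list's median was -0.25 (adjusted p = 1.9e-43, and 0.0480 with an estimated correlation), the only PFOS list call that held with an estimated correlation. PPAR targets leaned up by 0.07, with 1 of 24 higher when adjusted over the list alone (adjusted p = 6.9e-05, but adjusted p = 0.343 with an estimated correlation). NRF2 targets leaned up by 0.09 (adjusted p = 0.000193, but adjusted p = 0.784 with an estimated correlation), a call lost without control replicate 3 (0.0573). Cholesterol, lysosome, oxidative phosphorylation and cell cycle genes each had a median of 0.04 (adjusted p between 0.0077 and 0.0457, but adjusted p = 0.866 with an estimated correlation). Each of these 4 calls was lost without control replicate 1 (adjusted p = 0.0566, 0.0674, 0.398 and 0.322). Other omissions ended cholesterol (control replicate 3, 0.0780; PFOS replicate 3, 0.211), lysosome (PFOS replicate 2, 0.0669), oxidative phosphorylation (control replicate 3, 0.130; PFOS replicate 2, 0.847) and cell cycle (control replicate 2, 0.578; PFOS replicate 3, 0.660) calls. Every other list had an adjusted p of at least 0.127.

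Set directly against each other at the same mass concentration, PFOS and PFOA differed in the same 3 PPAR target genes. PDK4, PLIN2 and CPT1A were lower with PFOS than with PFOA, and no gene was higher. The interferon list, which lay below control in both groups, did not pass this test. By limma 0 genes were higher and 3 lower with PFOS, and edgeR and DESeq2 also gave 3. At an unadjusted p under 0.05 there were 823 genes where 1477 were expected by chance, which does not show that no other gene differed. The replicate block, which pairs these samples, gave the same 3. The molar concentrations were not equal (20 against 24.4 µM).

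PDK4 was lower with PFOS by a log2 difference of -1.77 [-1.96, -1.57] (adjusted p = 1.1e-11). PLIN2 differed by -0.72 [-0.86, -0.58] (adjusted p = 1.2e-06) and CPT1A by -0.34 [-0.44, -0.24] (adjusted p = 0.0028). CPT1A lost its call without PFOA replicate 3 (adjusted p = 0.0612) or PFOS replicate 2 (adjusted p = 0.0508). When these 6 libraries were fitted alone none of the 3 passed (adjusted p = 0.0634, 0.117 and 1). Intervals of genes that did not pass bound how far PFOS and PFOA could differ: FKBP5 0.02 [-0.10, 0.13], CD209 0.00 [-0.13, 0.14], CD86 -0.02 [-0.20, 0.17], CD83 -0.12 [-0.31, 0.07], HLA-DRA -0.01 [-0.20, 0.18], HMOX1 0.10 [-0.02, 0.22] and PPARG -0.04 [-0.24, 0.16]. For ANGPTL4 (-0.98 [-1.42, -0.54]) and FABP4 (-0.39 [-0.74, -0.03]) the single-gene interval excluded 0, but neither passed over all genes, except ANGPTL4 with the mitochondrial share as a covariate (adjusted p = 0.0453).

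The PPAR list was lower with PFOS, with 3 of 24 members lower over all genes, 6 adjusted over the list alone, and a median of -0.10 (adjusted p = 2.3e-19, and 0.00783 with an estimated correlation). Cell cycle genes were higher by 0.07 and cholesterol genes lower, with a median of -0.04 (adjusted p = 1.4e-05 and 0.0205, but adjusted p = 0.880 with an estimated correlation for both). The cell cycle call was lost without PFOA replicate 2 (0.0889) or PFOS replicate 3 (0.276), the cholesterol call without PFOA replicate 1 (0.132) or PFOS replicate 2 (0.270). With the replicate block, inflammatory and NF-kB genes (adjusted p = 0.034) and mitochondrial transcripts (0.037) were called as well, at the preset correlation. Without the block both had adjusted p = 0.880 with an estimated correlation. The interferon list had an adjusted p of 0.918, but was called lower without PFOS replicate 1 (median -0.05, 0.0056) and higher without PFOS replicate 2 (0.07, 0.0019).

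DEX reshaped the cells far more widely than any other exposure. Classical glucocorticoid receptor targets, cholesterol biosynthesis genes, metallothioneins and complement genes rose. Genes that mark IL-4-driven immature dendritic cells, MHC class II presentation and the monocyte lineage fell. The comparison gives a reference for DEX, a glucocorticoid, at the 1 dose used (150 µg/mL). It does not show how much of the response ran through the glucocorticoid receptor. By limma 3555 genes rose and 3455 fell, 7010 in all, of which 934 rose and 770 fell by more than 2-fold. The balance of rises and falls depended on the normalization: quantile normalization gave 3147 higher and 4274 lower, TMM scaling 3588 and 3405.

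Of the 12 largest rises, several were nearly silent in control. ZBTB16 went from 0.671 ± 0.582 to 1097 ± 93.8 normalized reads, DAAM2 from 0.696 ± 0.603 to 319 ± 20.8, SAA1 from 0.353 ± 0.611 to 171 ± 15.7, CHST1 from 0.680 ± 0.589 to 112 ± 30.4, and MMP7 from 0.696 ± 0.603 to 91.0 ± 2.52. Reads of SAA1 and its close copy SAA2 cannot be assigned with certainty. Among genes with a clear control level, FKBP5 rose from 2620 ± 32.4 to 131442 ± 10088 reads (log2 change 5.65 ± 0.06, adjusted p = 2.2e-29) and THBS1 from 91.8 ± 18.6 to 8668 ± 1234 (6.56 ± 0.13, adjusted p = 3.6e-23). AREG rose by 8.27 on the log2 scale, GNLY by 6.45, PDGFB by 5.91, RLN3 by 5.80 and C1QB by 5.65. The largest falls were in MMP13 (46.7 ± 1.03 to 1.77 ± 1.66 reads), IGF1 (-3.84), the chemokine CCL7 (819.8 ± 89.7 to 60.3 ± 3.11, 13.4-fold lower), SCN4B (-3.67), WNT7B (-3.62), ADAMTS5 (-3.58), BEX1 (-3.45), SERPINB2 (-3.43), CHDH (-3.41) and lysozyme, LYZ (56512 ± 2063 to 5684 ± 205, 9.94-fold lower, adjusted p = 2.7e-25). NHSL2 (-3.11) and NEGR1 (-3.06) completed them. None of these 24 calls was lost under any alternative or on leaving out any library.

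In the glucocorticoid receptor list 17 of 20 tested members rose and 1 fell, with the same counts adjusted over the list alone and a median of 2.08 (adjusted p = 4.4e-28, and 0.00379 with an estimated correlation). TSC22D3 rose 23.9-fold (13356 ± 532 against 558 ± 40.4 reads, adjusted p = 6.5e-24) and PER1 5.98-fold (3693 ± 107 against 616 ± 19.9). MERTK, chosen after its value was seen, was the member that fell (-0.42). Metallothioneins rose in 6 of 7 tested members, over all genes and adjusted over the list alone, by a median of 1.19 (adjusted p = 2.8e-09, and 0.00977 with an estimated correlation). MT2A led them with 10695 ± 1090 against 597 ± 53.9 reads, and reads of the near-identical MT1 genes cannot be assigned with certainty.

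Sterol genes moved together with DEX. In the cholesterol list 22 of 24 members rose and 1 fell, over all genes and adjusted over the list alone, with a median of 0.93 (adjusted p = 1.7e-29, and 0.00903 with an estimated correlation). SQLE (1.93), MSMO1 (1.87), STARD4 (1.69), IDI1 (1.21) and HMGCS1 (1.09) rose. TMEM97, chosen after its value was seen, was the member that fell (-0.26). Fatty acid synthesis genes rose in 8 of 12 members, including FADS2 (1.60) and SCD (0.35), by a median of 0.27 (adjusted p = 4.1e-06, but adjusted p = 0.0568 with an estimated correlation). PPAR targets split under DEX, with 9 of 24 higher and 2 lower (11 and 2 adjusted over the list alone; median 0.13, adjusted p = 5.6e-05, but adjusted p = 0.0880 with an estimated correlation). PDK4 rose 33.9-fold to 3960 ± 400 reads, ANGPTL4 26.1-fold to 464 ± 102, PLIN2 by 1.00 on the log2 scale to 19669 ± 1965, and PPARG by 2.03. CPT1A did not pass (-0.07, adjusted p = 0.40), and CD36 fell (-0.62), as did HILPDA (-0.27), chosen after its value was seen and lost with robust variance estimates (0.0571), DESeq2 (0.0823), and without control replicate 2 (0.132) or 3 (0.0905) or DEX replicate 1 (0.0652), 2 (0.0639) or 3 (0.0927).

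Dendritic cell identity genes mostly fell with DEX. CD209 (DC-SIGN) went from 9819 ± 198 to 1342 ± 123 reads (log2 change -2.87 ± 0.07, adjusted p = 6.2e-22). In the IL-4 response list 13 of 18 members fell and 3 rose, over all genes and adjusted over the list alone, with a median of -1.14 (adjusted p = 1.6e-09, and 0.0240 with an estimated correlation). CCL13 (-2.86), FCER2 (-2.30), FCER1A (-1.89), TGM2 (-1.65), CD1A (-1.17) and CLEC10A (-1.11) were among those that fell. The 3 that rose, chosen after their values were seen, were CCL17 (3.31), MRC1 (1.99) and SOCS1 (1.27). MHC class II genes fell in 9 of 12 members, 10 adjusted over the list alone, by a median of -0.91 (adjusted p = 6.1e-07, and 0.0188 with an estimated correlation). The class II transactivator CIITA went from 124 ± 4.30 to 21.9 ± 4.72 reads and HLA-DRA from 615 ± 25.3 to 205 ± 12.1. HLA-DPA1 (-1.34) and the invariant chain CD74 (-0.30) also fell. Monocyte markers fell in 11 of 12 members on either adjustment (median -0.86, adjusted p = 2.9e-16, and 0.00195 with an estimated correlation), with CTSG (-1.39), CD14 (-0.93), VCAN (-0.96) and S100A8 (-0.80). Dendritic cell markers fell in 7 of 11 members and rose in 2, FLT3 (3.06) and ZBTB46 (0.43, chosen after its value was seen), with 2 and 8 adjusted over the list alone (median -1.17, adjusted p = 0.000371, but adjusted p = 0.0568 with an estimated correlation).

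Maturation and inflammatory genes moved in both directions under DEX. CD86 fell from 1053 ± 75.2 to 445 ± 30.01 reads (adjusted p = 2.0e-11), whereas CD83 rose from 676 ± 107 to 1107 ± 140, and CD80 (adjusted p = 0.33) and CCR7 (0.98) did not pass. The maturation list had 7 of 17 members higher and 2 lower, CD86 and CD274 (-0.51, chosen after its value was seen), on either adjustment, with IDO1 at 111 ± 19.6 against 4.77 ± 0.477 reads. The CD274 call was lost without control replicate 2 (0.0918) or 3 (0.0810) or DEX replicate 1 (0.0834) or 3 (0.0537). Its median was 0.31 (adjusted p = 0.0419, but adjusted p = 0.436 with an estimated correlation), a call lost without control replicate 3 (0.135), DEX replicate 2 (0.0745) or DEX replicate 3 (0.0704). In the inflammatory and NF-kB list 11 of 23 rose and 3 fell, 12 and 4 adjusted over the list alone, with a median of 0.41 (adjusted p = 1.8e-06, but adjusted p = 0.145 with an estimated correlation). CCL20 (4.57), BIRC3 (3.94), TNFAIP3 (2.62) and NFKBIA (2.02) rose, whereas CCL2 (-2.17), IL6 (-2.11) and CXCL8 (-0.95), chosen after their values were seen, fell. Interferon genes fell in 15 of 23 and rose in 1, CXCL10 (1.95), on either adjustment (median -0.23, adjusted p = 2.1e-06, but adjusted p = 0.286 with an estimated correlation). Complement genes rose in 7 of 15 and fell in 1, CD55 (-0.48, chosen after its value was seen), on either adjustment (median 0.16, adjusted p = 1.7e-05, and 0.0188 with an estimated correlation), with C3AR1 (1.99), C5AR1 (1.78) and C1QA (1.73) among the rises. Tolerogenic genes rose in 7 of 14, 8 adjusted over the list alone, and fell in 4 (median 0.33, adjusted p = 0.00175, but adjusted p = 0.261 with an estimated correlation), with F13A1 (-1.96) falling and, chosen after their values were seen, IL10 (-1.76), GPNMB (-0.64) and STAB1 (-0.51). CD163 rose from 2677 ± 16.5 to 26647 ± 1977 reads. Phagocytic receptors as a list fell in 8 of 15, 9 adjusted over the list alone, and rose in 2 (median -0.42, adjusted p = 0.00177, but adjusted p = 0.154 with an estimated correlation), FCGR3A (-1.72), FCGR2B (-1.54) and FCGR1A (-1.26) among the falls.

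**Figure D2:**
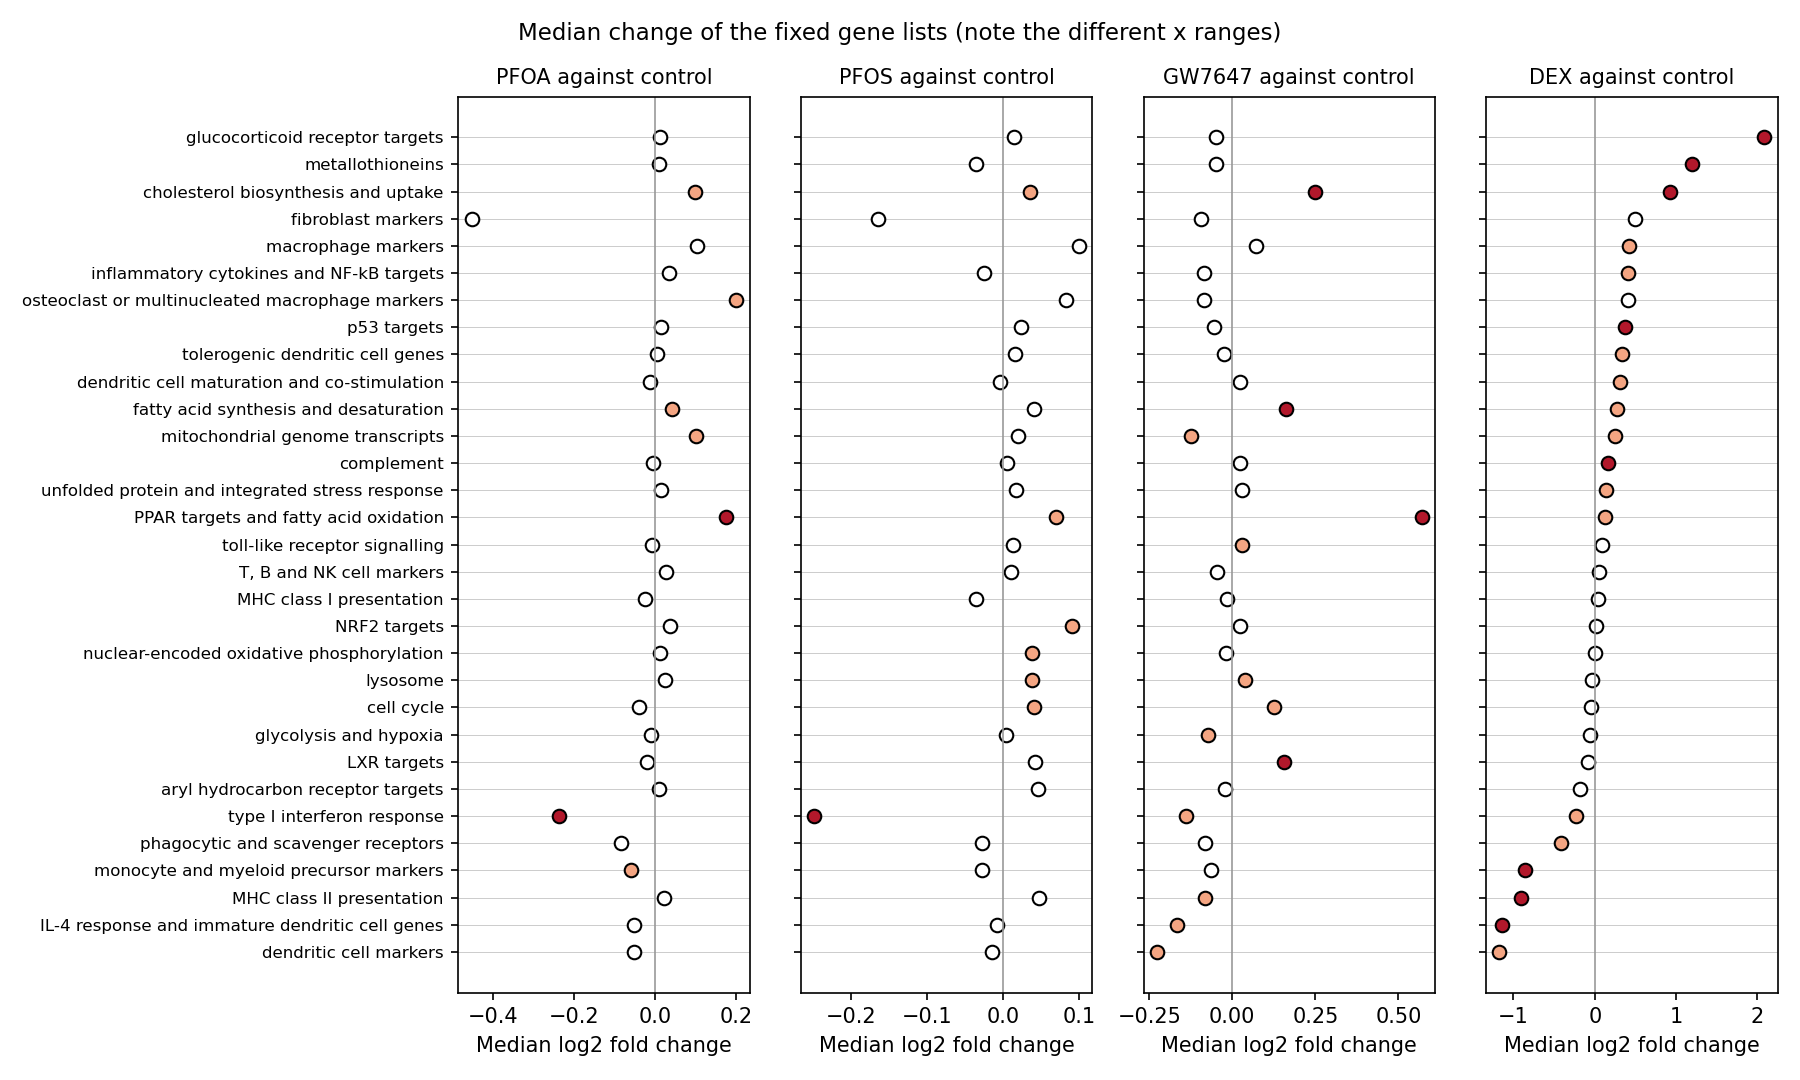
Median log2 change of the 31 tested gene lists in PFOA, PFOS, GW7647 and DEX against control, 1 panel each with its own scale. Open points were not called, light orange points were called at the preset correlation only, and dark red points were also called with an estimated correlation (2, 1, 4 and 8 lists in that order).

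GW7647 raised PPAR targets further than PFOA did. Adjusted over the list alone, as many members of the PPAR list rose with PFOA as with GW7647, so the difference shown is one of size. The list of PPAR targets and fatty acid oxidation rose, with the lipid droplet gene PLIN2 and the fatty acid transporter gene CD36 among its members, and the cholesterol, fatty acid synthesis and LXR target lists rose with it. Falls were small, and 11 of the 12 largest were lost without control replicate 2. All 12 held with the replicate block, which pairs these samples. The comparison gives a reference for GW7647, an agonist of PPARα, but does not show which receptor carried the response. By limma 114 genes rose and 41 fell, 155 in all, and 11 rose by more than 2-fold and 0 fell by that much. The count fell to 98 without GW7647 replicate 2 and to 99 without control replicate 2.

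PDK4 rose 32.8-fold to 3818 ± 311 reads (log2 change 5.03 ± 0.09, adjusted p = 1.1e-22). FABP4 rose 17.4-fold to 1482 ± 194 (4.12 ± 0.17, adjusted p = 9.3e-15), PLIN2 7.29-fold to 71547 ± 5788 (2.87 ± 0.07, adjusted p = 1.4e-20), ANGPTL4 5.73-fold to 101.02 ± 23.2 and CPT1A 2.54-fold to 10859 ± 456 (1.35 ± 0.05, adjusted p = 2.9e-16). The other large rises were PDK4-AS1 (49.2 ± 16.4 against 5.71 ± 3.39 reads), GUCY1A2 (1.29), ACAA2P1 (1.19), OCLN (1.13), ACAA2 (0.99), ABCA1 (0.94) and CD300A (0.92). PDK4-AS1 is antisense to PDK4 and ACAA2P1 is a pseudogene of ACAA2, so their reads may belong to those genes, strand use in the counting not being given. No rise among these 12 was lost on leaving out a library, and fitting GW7647 and control alone lost 3 of them (PDK4-AS1, ACAA2P1 and OCLN). CD36 (0.73) rose too. PPARG did not pass (0.40, adjusted p = 0.064), but did with the replicate block (0.019), robust variance estimates (0.0383), array weights (0.0323), DESeq2 (0.0357), the mitochondrial covariate (0.0386) and without control replicate 1 (0.0256). FKBP5 (0.18), CD86 (-0.16), HLA-DRA (-0.27) and CD209 (-0.05) did not pass.

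The 12 largest falls were FCGR2C (-0.68), FCGR1BP (-0.66), HSPA7 (-0.66), FMNL1-DT (-0.63), U2AF1 (-0.62), FCRLB (-0.53), TNFSF13 (-0.51), ADAM19 (-0.50), ITGB2-AS1 (-0.50), BDH1 (-0.50), FCGR2B (-0.48) and HSPA6 (-0.46). FCGR2B went from 2472 ± 289 to 1766 ± 189 reads and HSPA6 had an adjusted p of 0.0032. With the replicate block and all libraries, each of the 155 main calls held, these 12 included. That fit called 210 genes, 138 higher and 72 lower. In fits without the block these falls were fragile: 11 of the 12 calls, all but HSPA6, were lost without control replicate 2 (adjusted p from 0.0522 to 0.199). Leaving out control replicate 1 lost 7, control replicate 3 lost 6, GW7647 replicate 1 lost 6, and GW7647 replicates 2 and 3 lost 7 each, with adjusted p up to 0.288. Fitting GW7647 and control alone lost 10 of the 12 (adjusted p up to 0.450), and robust variance estimates lost 5 (up to 0.451). Reads of U2AF1 are uncertain because 94.3% of its 50-base words also occur in transcripts of another gene, as are those of FCGR2C (44.9%), HSPA7 (56.3%), HSPA6 (45.5%) and FCGR2B (16.15%). For FCGR1BP this share could not be measured, because its identifier is not in the transcript set used, but 73.6% of the words of its relative FCGR1A are shared, so its reads are uncertain too. ITGB2-AS1 and FMNL1-DT lie against other genes, whose reads could not be told apart from theirs without strand.

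Lipid lists dominated the GW7647 response, and 4 list calls held with an estimated correlation. PPAR targets rose in 15 of 24 members, over all genes and adjusted over the list alone, by a median of 0.57 (adjusted p = 9.9e-78, and 1.8e-05 with an estimated correlation). Cholesterol genes rose in 11 of 24, 18 adjusted over the list alone, by 0.25 (adjusted p = 2.6e-35, and 0.00698 with an estimated correlation), including DHCR7 (0.53), IDI1 (0.34) and SREBF2 (0.31), and HMGCS1 (0.30). The HMGCS1 call was lost without control replicate 3 (adjusted p = 0.0552), and that of IDI1 when GW7647 and control were fitted alone (0.0775). Fatty acid synthesis genes rose in 3 of 12, FADS2 (0.73), SCD (0.53) and FADS1 (0.45), with 7 adjusted over the list alone (median 0.16, adjusted p = 3.1e-12, and 0.0137 with an estimated correlation). LXR targets rose in 3 of 11, 4 adjusted over the list alone, by 0.15 (adjusted p = 5.2e-08, and 0.00698 with an estimated correlation). Of these 3, LPCAT3 (0.31) was lost without control replicate 3 (0.0589) or GW7647 replicate 1 (0.0679) or 2 (0.0505), and when the 2 groups were fitted alone (0.183). Cell cycle genes leaned up by 0.13, with 0 of 24 past the threshold over all genes and 11 adjusted over the list alone (adjusted p = 1.4e-13, but adjusted p = 0.201 with an estimated correlation). Interferon genes leaned down by a median of -0.14, with 1 of 23 lower, STAT2 (-0.31, lost when the 2 groups were fitted alone, 0.101), and 8 adjusted over the list alone (adjusted p = 5.9e-11, but adjusted p = 0.247 with an estimated correlation). Dendritic cell markers (median -0.23, ITGAX lower by -0.39, lost in the same fit, 0.1096) and IL-4 response genes (-0.17) also leaned down (adjusted p = 0.000278 and 0.000406, but adjusted p = 0.0842 and 0.247 with an estimated correlation), the second lost without GW7647 replicate 3 (0.0991). Glycolysis, mitochondrial, MHC class II, lysosome and toll-like receptor lists were called at the preset correlation (adjusted p = 9.5e-05, 0.0135, 0.0141, 0.0232 and 0.0481, but adjusted p from 0.268 to 0.742 with an estimated correlation). All of these but glycolysis were lost on leaving out single libraries. Without GW7647 replicate 1 the mitochondrial (0.752), lysosome (0.234) and toll-like receptor (0.220) calls ended, as they did without GW7647 replicate 2 (0.624, 0.218 and 0.445). The MHC class II call ended without control replicate 1 (0.0685) or GW7647 replicate 3 (0.203), the lysosome call without control replicate 1 (0.0989) or 3 (0.0502), and the toll-like receptor call without control replicate 3 (0.308). The replicate block, which pairs these samples, added inflammatory and NF-kB genes (adjusted p = 0.015) and tolerogenic genes (0.037) at the preset correlation. Without the block these had adjusted p = 0.782 and 0.716 with an estimated correlation.

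**Figure D3:**
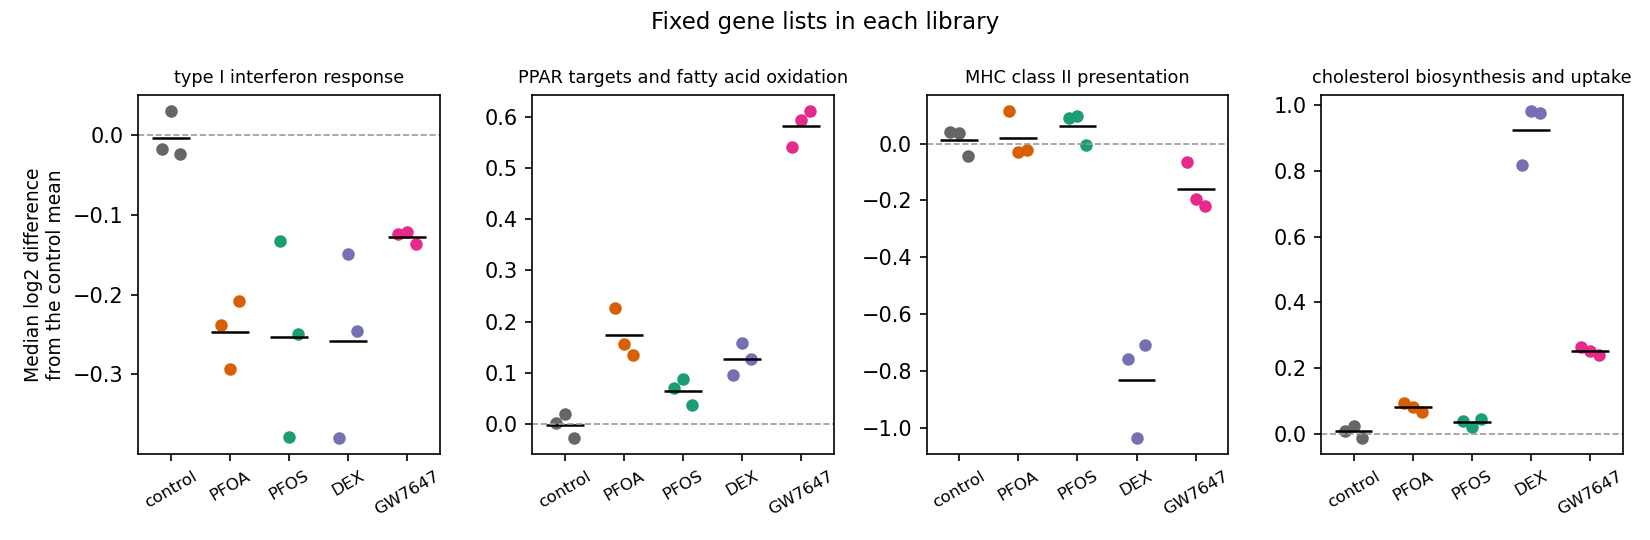
Median log2 difference from the control mean of the type I interferon, PPAR target, MHC class II and cholesterol lists in each library (points) of the 5 groups, with group means as lines. Interferon medians were -0.29 to -0.21 with PFOA and -0.38 to -0.13 with PFOS, against -0.02 to 0.03 in control.

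Direct tests of the PFAS groups against the reference compounds asked whether the responses differ. Relative to GW7647, PFOA had 20 genes higher and 83 lower by limma, and PFOS 36 higher and 96 lower. PPAR targets were lower with either PFAS: PDK4 by a log2 difference of -3.06 with PFOA and -4.83 with PFOS, FABP4 by -3.31 and -3.70, PLIN2 by -1.83 and -2.56, ANGPTL4 by -1.77 and -2.75, CPT1A by -1.02 and -1.35, and ABCA1 by -0.78 and -0.85, all past the threshold. The PFOA count of 103 was 40 without PFOA replicate 2, 50 without GW7647 replicate 1 and 45 without GW7647 replicate 2, and the PFOS count of 132 was 81 without PFOS replicate 2 and 80 without GW7647 replicate 2. The PPAR list was lower with PFOA by a median of -0.35, with 14 of 24 members lower and 15 adjusted over the list alone (adjusted p = 0.00014 with an estimated correlation), and lower with PFOS by -0.48, with 15 members lower (2.6e-05 with an estimated correlation). Cholesterol genes were lower with PFOS than with GW7647 by a median of -0.18, in 7 of 24 members and 16 adjusted over the list alone (adjusted p = 0.0126 with an estimated correlation). Relative to DEX, 7055 genes differed with PFOA and 7195 with PFOS. FKBP5 was lower by -5.65 and -5.63, while CD209 was higher by 2.86 in both and LYZ by 3.13 and 3.26. PLIN2 did not differ detectably between PFOA and DEX (0.03 [-0.11, 0.17], adjusted p = 0.80), and was lower with PFOS than with DEX (-0.69).

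Sharing the 3 control libraries alone gave high correlations between whole responses. The simulated genes varied independently, unlike real ones, so the highest draws are too narrow a limit and no excess over them can be read. On leaving out single libraries, r of PFOA and PFOS ran from 0.4625 to 0.631. Across 29545 genes, which are not independent replicates, the log2 changes of PFOA and PFOS correlated with r = 0.532, against 0.50 in simulated unchanged groups (highest of 100 draws 0.515), with a covariance of 0.0794 against 0.0722 (highest 0.0748). For PFOA and GW7647 r was 0.484 against 0.50, with a covariance of 0.0760 against 0.0722, no higher than the highest draw (0.07598). For PFOS and GW7647 r was 0.489 against 0.50, with a covariance of 0.0763 against 0.0723 (highest 0.0755). For DEX, r was 0.294 with PFOA, 0.285 with PFOS and 0.292 with GW7647 (against 0.50 simulated for each; covariances 0.0753, 0.0726 and 0.0781, against 0.0723, 0.0723 and 0.0722 simulated, with highest draws of 0.0750, 0.0763 and 0.0752). All 3 genes raised by PFOA were raised by GW7647 (0.0116 expected from independent lists), and 2 of them, PDK4 and PLIN2, by DEX (0.361 expected). DEX and GW7647 shared 57 genes raised (13.7 expected) and 20 lowered (4.80 expected), and part of that excess may come from the shared controls, which at 3 libraries cannot be split. Across all 5 groups, limma's F test found 6817 genes with any difference.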

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

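The test of carry-over from GW7647 and the test of the mitochondrial share for the PPAR genes were chosen only after the result was seen. A direct test of the difference between PFOS and PFOA picked out 4 results for a closer look. PDK4 was lower with PFOS than with PFOA by a log2 difference of -1.77, PLIN2 by -0.72 and CPT1A by -0.34 (limma's adjusted p = 1.1e-11, 1.2e-06 and 0.0028). The list of PPAR targets was lower with PFOS by a median of -0.10 (camera's adjusted p = 0.00783 with an estimated correlation).

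The PPAR targets higher in PFOA than in both PFOS and control could come from a technical source, and 2 were weighed. Carry-over of material from the GW7647 samples would raise every gene by 1 common fraction of its GW7647 rise. The fractions of the 11 genes raised over 2-fold by GW7647 differed beyond their errors (chi-square test of heterogeneity on limma's estimates, p = 1.8e-09), with 16.6% ± 1.32 for PLIN2, 16.7% ± 2.41 for CPT1A, 9.22% ± 0.735 for PDK4 and 4.91% ± 1.14 for FABP4, which argues against it as the whole cause. With the share of mitochondrial reads as a covariate the PDK4 difference between PFOS and PFOA was -1.80 instead of -1.77. That share overlapped between the groups (2.28% to 2.49% with PFOA, 2.2% to 2.42% with PFOS). The covariate could thus take up little of the difference, and the fit says little about this source. A compound effect of PFOA on PPAR target genes remains as a hypothesis, as do the unequal molar doses (24.4 and 20 µM), which were not tested.

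Other splits of the 6 samples of each comparison into groups of 3 number 10, too few for a share under 0.05. In PFOA against control the real split gave 3 genes and the highest other split 29, so that 2 of the 10 splits gave at least 3. That other split set PFOA replicates 1 and 2 and control replicate 2 against the rest, which points to a structure of these samples beyond their groups. In PFOS against control all 10 splits gave 0 genes. For the others only 1 split, the real one, gave as many genes: DEX against control 7010 (highest other 0), GW7647 against control 155 (0), PFOS against PFOA 3 (2), PFOA against GW7647 103 (1), PFOS against GW7647 132 (1), PFOA against DEX 7055 (0) and PFOS against DEX 7195 (0). Where the replicate numbers pair the samples, 4 of the 10 splits part all 3 pairs, and the highest of these other than the real one was 0 in PFOS against control, GW7647 against control and PFOS against PFOA. The split with 2 genes in PFOS against PFOA parted 1 pair. For any difference among the 5 groups, 1 of 100 regroupings of the 15 samples, the real one with 6817 genes, gave as many (highest other 0). Regroupings that part the DEX libraries also widen the spread within groups, so few calls in them were likely from the start. The test takes all groups at once and does not bear on the PFAS groups alone. If the replicates are technical, differences between single cultures would give the same outcome, so chance at that level is not excluded.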

How the results depend on the processing

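TMM scaling, voom, the mitochondrial share as a covariate and the fit without the DEX samples were tests chosen after seeing the data, and the others were fixed before. No named gene reversed direction under any of them where the main fit or the alternative called it. Directions of genes called in neither were not compared. No scaling moved the median change of all genes by over 0.1. PDK4 and PLIN2 passed in PFOA against control under every alternative and omission. The PDK4 change there ranged from 1.9 to 2.05 over the alternatives and omissions. Median-of-ratios scaling moved almost nothing (7196 instead of 7195 genes in PFOS against DEX and no other count of genes or lists), because the deposited values already have it, so it says nothing about stability. Of the gene results compared over the alternatives other than omissions, those that kept their side of the threshold were 2113 of 2126 for PFOA, 2155 of 2170 for PFOS, 2433 of 2483 for DEX, 2230 of 2323 for GW7647 and 2102 of 2106 for PFOS against PFOA.

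Counts of called genes that moved by over 1.5 times were these. With the replicate block, PFOA gave 8 genes, PFOS 4 and PFOA against GW7647 281, and the block changed no other count of genes by that much. In the comparisons whose samples it pairs, it changed no call named in the report other than those given there. By the limit of 0.1 for every pair, the numbers did not pair PFOA or DEX with control (lowest correlations -0.0105 and -0.0665). For PFOA and control, replicates 1 and 3 correlated at 0.284 and 0.393, and only replicate 2 fell short. Since 13 of the 15 libraries correlated best with their own number, a partial pairing there cannot be excluded, and the main fit leaves any pairing out. With DESeq2, PFOA gave 14, PFOS 13 and PFOA against GW7647 257. With the mitochondrial share as a covariate, PFOA gave 10, PFOS 3, PFOS against PFOA 5, PFOA against GW7647 179 and PFOS against GW7647 201. Array weights gave 204 for PFOA against GW7647. Fits of the compared groups alone gave 53 for GW7647, 0 for PFOS against PFOA, 13 for PFOA against GW7647 and 19 for PFOS against GW7647, with fewer samples to estimate the spread. At a threshold of 0.01 these were 94 for GW7647, 54 for PFOA against GW7647 and 83 for PFOS against GW7647. The cause of the other shifts was not tested.

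On leaving out single libraries the counts ranged from 2 to 5 for PFOA, 0 to 1 for PFOS, 98 to 173 for GW7647, 40 to 113 for PFOA against GW7647 and 80 to 112 for PFOS against GW7647, and stayed within 1.5 times for DEX (5958 to 6680), PFOS against PFOA (2 to 3) and the F test (5503 to 7011). Called lists ranged from 4 to 12 for PFOA, 3 to 8 for PFOS and 2 to 8 for PFOS against PFOA. With an estimated correlation 2 lists were called for PFOA, 1 for PFOS, 8 for DEX, 4 for GW7647 and 1 for PFOS against PFOA, and with the replicate block 5 for PFOS against PFOA. Among lists called in the main test or on an omission, the direction of the list test reversed in 3 cases, given with the range of medians over the omissions. Oxidative phosphorylation in PFOS ranged from -0.0025 to 0.0686, cell cycle in PFOS from 0.0012 to 0.0783, and interferon in PFOS against PFOA from -0.0506 to 0.0670. In genes above the median mean value the correlations with the DEX response were 0.131 for PFOA, 0.0890 for PFOS and 0.133 for GW7647, but no unchanged groups were simulated for these genes, so the drop from the values over all genes cannot be read. In simulated reads at this depth, 46% of the genes given the smallest change, none of them from the lowest levels, were recovered for either PFAS.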

Other observations

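The comparison of the interferon genes with GW7647 and the test of PFOS against PFOA over genes raised by GW7647 were tests chosen only after the result was seen, and those with the mitochondrial share and with the other sets of GW7647 genes were added after the data were seen. With DEX, p53 targets rose in 7 of 12 members, over all genes and adjusted over the list alone, by a median of 0.37 (camera's adjusted p = 3.8e-06, and 0.0103 with an estimated correlation), with SESN1 (1.65), CDKN1A (0.96) and TP53I3 (0.81). Stress response genes rose in 8 of 20 and fell in 2, 10 and 2 adjusted over the list alone (median 0.13, adjusted p = 0.000393, but adjusted p = 0.177 with an estimated correlation), with DDIT4 (3.97) and HERPUD1 (2.37) up and DDIT3 (-0.37) and TRIB3 (-0.26), chosen after their values were seen, down. The DDIT3 call was lost when DEX and control were fitted alone (adjusted p = 0.0611). Macrophage markers rose in 6 of 12 and fell in 2, 3 adjusted over the list alone (median 0.42, adjusted p = 0.000461, but adjusted p = 0.130 with an estimated correlation), MARCO (-1.12, chosen after its value was seen) among the falls. Mitochondrial genome transcripts rose in 4 of 13 on either adjustment (median 0.25, adjusted p = 0.0110, but adjusted p = 0.521 with an estimated correlation), a call lost without DEX replicate 1 (0.209). That library had the highest mitochondrial share (2.98%), and without it all 4 genes lost their calls (adjusted p from 0.0617 to 0.358), as they did with robust variance estimates or quantile normalization.

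The remaining lists were not called with DEX, though some members moved. Glycolysis genes fell in 5 of 16 on either adjustment (median -0.06, adjusted p = 0.094), HK2 by -1.14, with PKM lost without control replicate 2 (0.0562) or when DEX and control were fitted alone (0.0724), and the list was called without control replicate 3 (0.0176) or DEX replicate 2 (0.0169). Lysosome genes rose in 4 of 19 and fell in 6, 5 and 7 adjusted over the list alone (median -0.04, adjusted p = 0.094), CTSL falling (-1.35) and CTSB rising (0.46), with a call without DEX replicate 2 (0.0283). Toll-like receptor genes rose in 7 of 15 and fell in 3 on either adjustment (0.09, adjusted p = 0.0965), with TLR2 (1.47) up and TLR8 (-1.43) down. LXR targets rose in 1 of 11 and fell in 5 (-0.08, adjusted p = 0.151), the cholesterol exporters ABCA1 (-1.71) and ABCG1 (-1.91) among them. NRF2 targets rose in 7 of 17 and fell in 3 (0.01, adjusted p = 0.156; 0.0434 without DEX replicate 1), GCLC (1.81) and AKR1C1 (1.33) up and HMOX1 (-0.88) down. Cell cycle genes rose in 3 of 24 and fell in 8, 6 and 8 adjusted over the list alone (-0.05, adjusted p = 0.189), with MCM2 (-0.41) and MCM4 (-0.39) down. MHC class I genes rose in 5 of 15 and fell in 2, 7 and 3 adjusted over the list alone (0.04, adjusted p = 0.309). Aryl hydrocarbon receptor targets rose in 3 of 8 and fell in 1 (-0.18, adjusted p = 0.595), and oxidative phosphorylation genes rose in 1 of 25 and fell in 3 (0.00, adjusted p = 0.885). The member NQO1, counted as a rise in both the NRF2 and aryl hydrocarbon receptor lists, was lost without control replicate 1 or 3 or DEX replicate 2 or 3 (adjusted p from 0.111 to 0.229). All 3 oxidative phosphorylation falls were lost without control replicate 2 (UQCRC1 0.199, UQCRFS1 0.0633 and NDUFS3 0.133), and the rise, COX5B, without control replicate 1 or 3 or DEX replicate 2 or 3 (0.0621 to 0.101). Lymphocyte markers rose in 2 of 8 (0.05, adjusted p = 0.189), NKG7 (0.56) and GNLY, osteoclast markers rose in 2 of 5 and fell in 1 (0.41, adjusted p = 0.309), with DCSTAMP up (2.13) and OCSTAMP (0.75) lost on leaving out any of 4 libraries (adjusted p from 0.106 to 0.204), and fibroblast markers changed in 0 of 4 (0.50, adjusted p = 0.455).

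Interferon response genes lay lower than control in both PFAS groups, with a median log2 change of -0.24 in their mean and all 23 genes negative (camera's p = 0.00079 with an estimated correlation). With the mitochondrial share as a covariate the median stayed at -0.24 (camera's p = 0.0011, likewise with an estimated correlation). That share overlapped between control and both PFAS groups, so the covariate could take up little and the fit says little about this source. Control libraries that happened to stand high would lower every treated group alike, and the DEX median of -0.23 goes with that, though DEX may act on these genes itself. The PFAS groups lay below GW7647 in 22 of 23 genes by a median of -0.11, but that test did not pass (p = 0.102 with an estimated correlation), and GW7647 itself lay at -0.14 against control (p = 0.064). High controls and a PFAS effect therefore cannot be told apart here, because the comparison with GW7647, which uses no control library, did not pass, and either may account for the pattern.

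Of the 12 largest falls with GW7647, 5 (HSPA6, FCGR2C, HSPA7, FCGR2B and FCRLB) lie in 204 kb of chromosome 1 (161524540 to 161728143, GRCh38), which holds 10 tested genes. Of all 41 genes that fell, 40 could be placed and only these 5 lie there. In 10000 random draws of 40 tested genes no window of that width held over 3 (permutation p = 0.0001, the smallest these draws can give). The width was taken from these same 5 genes after they were seen. The draws also pick genes independently, whereas 4 of the 5 share sequence with other genes. That p-value therefore does not exclude chance placement. Shared reads between copies could move such genes together: 0% of the 50-base words of FCRLB occur in transcripts of another gene, which argues against that source for FCRLB, but the share is 16.15% for FCGR2B and 44.9% to 56.3% for FCGR2C, HSPA6 and HSPA7 (median of the 4 45.2%), so for them it cannot be told apart from a change of each gene. FCGR3A (0.46) and FCRLA (-0.27), chosen after their values were seen, lie in the same segment and did not pass. All 5 calls but HSPA6 were lost without control replicate 2, and all 5 held with the replicate block. In DEX the same 5 genes fell as well, by -0.46 to -1.86. FCGR3A (-1.72) and FCRLA (-1.91) fell there too, so the fall with DEX is not particular to the 5. Both comparisons use the same control libraries.

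A hypothesis was that PFOA or PFOS weakly raises what GW7647 raises, beyond PDK4, PLIN2 and CPT1A, tested on genes picked in libraries outside each test. Of 93 genes higher in GW7647 than in PFOS, 85 were higher in PFOA than in control, with a median log2 change of 0.12 (p = 0.0013 by camera from limma with an estimated correlation), consistent with a weak shared response to PFOA. Of 80 genes higher in GW7647 than in PFOA, 51 were higher in PFOS than in control, with a median of 0.03 (p = 0.387 by the same test and estimated correlation), which leaves PFOS undecided. Over 111 genes raised by GW7647, PFOS lay below PFOA in 93, by a median of -0.07 (p = 0.015, estimated correlation).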
